A study of Drosophila melanogaster with 25 samples.

How the data were processed

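RNA that came down with a protein from nuclear extracts was sequenced by RIP-seq. In this method an antiserum pulls a protein out of the extract, and the RNA that comes with it is made into libraries. The labels describe preclearing with preimmune serum, selection of polyadenylated RNA and Illumina sequencing, and name antiserum Gp60 against Su(Hw) and antisera Rb5, Rb6 and Gp01 against Shep. Input libraries were made from the same kind of extract without precipitation. No library from a mock precipitation was used here, so each precipitate is set against input alone.

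The authors deposited 1 table of raw read counts per gene for each sample, with Drosophila FBgn identifiers and no symbols. Per the submitters' processing notes, the tools used were cutadapt 1.2.1, TopHat2, Bowtie2, HTSeq and DESeq, and the genome build was dm3. The annotation release, the strand setting of the counting and the steps each tool was used for are not given in the sources used here. Counts of overlapping and antisense genes are therefore uncertain, because reads of both partners cannot be told apart without strand. The tables also hold lines for reads that match no gene, several genes or several places. These lines name no gene and were left out of library sizes and tests. They held between 50.2% and 91.2% of all lines' counts in a library, and reads placed in more than 1 position alone held between 35.0% and 86.6%.

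Samples were grouped by cell line, protein and antiserum as their labels give them. Of the 25 samples, 3 Kc samples (input 3, Shep Rb5 3 and Su(Hw) 2) were each listed 2 times with identical files and were counted once, which left 22 libraries in 8 groups. The labels call the samples biological replicates, and every p-value rests on that statement. The labels also name the sequencer and the quality encoding, and 4 sequencing classes were made from them. The mixed class is that of the samples listed for both machines with identical files. Class GA II holds Kc inputs 1 and 2, Rb5 1 and 2 and Su(Hw) 1, and a mixed class of GA II and HiSeq holds input 3, Rb5 3 and Su(Hw) 2. HiSeq with PHRED64 qualities holds inputs 4 and 5, Gp01 1, Rb6 1, Su(Hw) 3 and all BG3 libraries, and HiSeq with PHRED33 qualities holds input 6, Gp01 2 and Rb6 2.

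Differences were tested with edgeR's quasi-likelihood test in its robust form (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling, 1 mean per group and the sequencing class as a covariate, over all 22 libraries. Genes were kept by edgeR's filter with a minimum count of 10 and a minimum total of 15, which left 9961 of 16037 gene identifiers. There were 11 comparisons, each adjusted over the tested genes by the Benjamini-Hochberg method at 0.05. A gene that passed is called here. Folds are on the log2 scale from the edgeR fit at its default prior count, so folds at low counts are little shrunk. A prior count of 2 entered only log2 CPM values. These served the principal components, the folds within classes, the pairing check, the correlations of single libraries and the rule for named genes. Levels are CPM, which are counts scaled to a common library size, scaled by TMM. All folds are relative to the other RNAs of a library, since no spike-in was used here.

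Gene symbols came from a RefSeq gene table of assembly GCF_000001215.4, used for names only. It paired 172 of the identifiers, or 1.07%, with a symbol, and 80 of these were among the tested genes. That assembly is not the build of the counts, so no coordinates are given. The rule for named genes, the comparisons, the gene lists and the alternatives chosen first were fixed before the data were examined. The rule takes the 10 largest rises and the 5 largest falls of each comparison with input among called genes with at least 10 CPM in 1 of the groups and every precipitate on the same side (5 each way between cell lines). It was applied among genes that have a symbol, and the largest changes of all genes therefore lie mostly among genes that are not named here. Genes given by identifier alone, and others outside the rule, were chosen after their values were seen.

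The 17 gene lists covered insulator proteins, RNA-binding proteins, ribosomal proteins, oxidative phosphorylation, the proteasome, neuronal and neuroblast genes, haemocyte genes, axon guidance and adhesion, Polycomb and trithorax groups, ecdysone response, cell cycle, heat shock, nuclear noncoding RNAs, the mitochondrial genome, muscle, fat body and germline. Because of the few symbols, 0 lists reached the 5 members set for a list test, so limma's camera test and its alternatives were not run and no count adjusted over a list alone is given. Checks of GC content and gene length were void, since too few genes have a value.

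The alternatives fixed then were RLE size factors, DESeq2 1.42.0, no filter on low counts, no sequencing class, the replicate number as a block in place of the class, only the compared groups, only GA II or only HiSeq libraries, and leaving out each library in turn. Alternatives added after seeing the data were limma voom with group quality weights, leaving out the most abundant identifier FBgn0085813, only genes at 10 CPM or more in the inputs, and leaving out Su(Hw) libraries Kc 1, Kc 2 and BG3 1. A choice of genes by input level leaves out RNAs low in the inputs, which can by itself favour falls against input. The direct tests between antisera and the tests of library composition were also added then. The replicate block gives 1 effect to all libraries of like number, across cell lines, antisera and sequencing classes. Rb6 2 and Gp01 2, for example, share a block with Kc input 2, which is of another class. The block is therefore not an adjustment for pairs within a comparison. Genes that DESeq2 left without an adjusted p stayed so. Where leaving out a library left 1 in a group, that lone sample is assumed to vary like the other groups.

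Pairing by replicate number was checked by correlating deviations from the group means. Kc Rb5 and input numbers deviated together (r = 0.49, 0.31 and 0.31 across genes). Su(Hw) and input numbers did not (r = -0.08, 0.04 and -0.35), nor did Kc Rb5 and Su(Hw) numbers (r = -0.14, -0.05 and -0.21). Like numbers of Rb5 and input also share their sequencing class, and correlations between unlike numbers were not computed. Pairing of Rb5 with input is therefore possible but not shown. The other groups compared share fewer than 3 numbers. In BG3 cells like numbers deviated together, at r = 0.64 for input and Rb5, 0.34 for input and Su(Hw) and 0.41 for Rb5 and Su(Hw). With 2 libraries per group, both numbers give the same r. All BG3 libraries share 1 sequencing class, so pairing is possible there too. The main test takes no account of it. Comparisons against shared inputs were set beside 12 simulations of unchanged groups and 20 splits of the inputs. The test was tested on counts simulated from the model fitted to these libraries, over 9961 genes. Each precipitate was set equal to its input, except for 100 genes changed at each fold size. The real comparisons with input called far more genes, so the false shares given next need not hold for them. For Kc Rb5 against input it recovered 33% of 2-fold and 68% of 4-fold changes with 2.88% of calls false. The matching values were 22%, 82% and 6.31% for Rb6, 42%, 69% and 5.93% for Kc Su(Hw), and 9%, 64% and 7.59% for BG3 Rb5. Further computing used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.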

Results

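RNA recovered from nuclear extracts with antisera against Su(Hw) and against Shep was measured in 2 Drosophila cell lines. Su(Hw) is a zinc-finger DNA-binding protein of the gypsy insulator, and Shep is an RNA-binding protein. Kc cells are an embryonic line with blood-cell properties, and BG3 cells derive from the larval central nervous system. In Kc cells there were 6 inputs, 3 Su(Hw) precipitates (antiserum Gp60) and Shep precipitates with antisera Rb5 (3 libraries), Rb6 (2) and Gp01 (2). In BG3 cells there were 2 inputs, 2 Su(Hw) and 2 Shep Rb5 precipitates. Counts assigned to genes ran from 8326741 to 44773161 in the Kc inputs, from 12455645 to 59066733 with Rb5 and from 6190633 to 46077295 with Kc Su(Hw). They were 46893917 and 53154028 with Rb6 and 40008034 and 24423074 with Gp01. In BG3 cells they were 44147921 and 35270932 in the inputs, 43488976 and 45411211 with Rb5, and 25625321 and 48754771 with Su(Hw). In the text, levels are mean CPM ± SD over libraries and folds are log2 values ± SE from edgeR.

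The 22 libraries separated first by cell line. On the first principal component of log2 CPM, which held 57.7% of the variance, BG3 libraries lay between -144 and -134 and Kc libraries between 37.6 and 63.1. The second component held 9.98%.

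**Figure D1:**
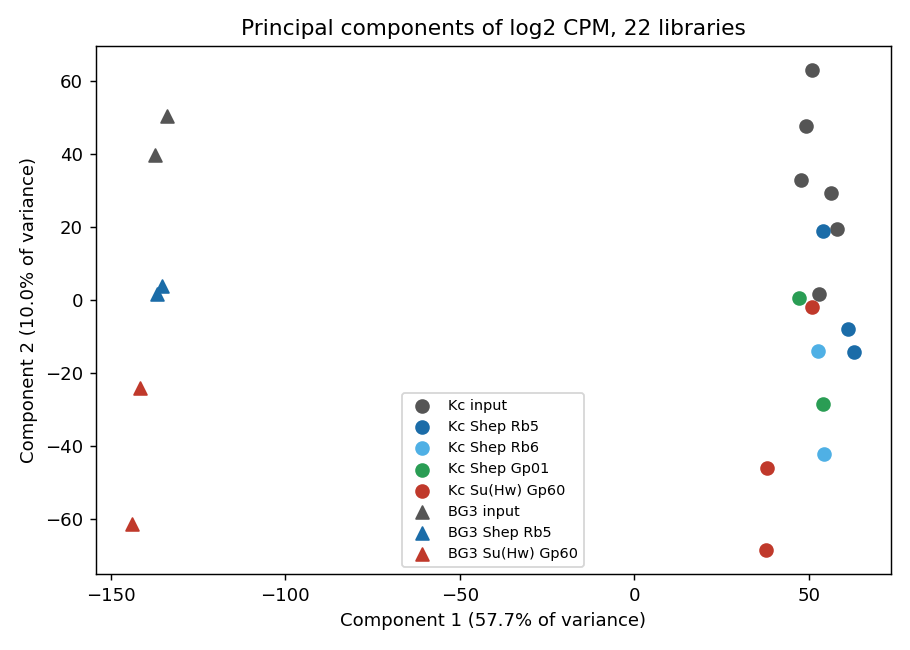
Principal components of log2 CPM for the 22 libraries, with 1 point per library, coloured by group, and axes in component units with the percent of variance. BG3 libraries lie between -144 and -134 on the first component and Kc libraries between 37.6 and 63.1.

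The first comparison asks which RNAs Shep antiserum Rb5 recovered from Kc nuclei beyond their share of the input. Idgf3 (FBgn0020414), a secreted growth factor of the chitinase-like family, stood at 39.3 ± 8.33 CPM (n = 3) with Rb5 and 162 ± 29.5 CPM (n = 6) in the inputs, a log2 fold of -1.96 ± 0.24 (edgeR adjusted p = 2.07e-05). Mau2 (FBgn0038300), part of the cohesin loader, fell by 1.36 ± 0.28 on the log2 scale, and Prp31 (FBgn0036487), a U4/U6 snRNP splicing factor, fell by 1.16 ± 0.21 from 74.9 ± 18.2 to 38.6 ± 3.35 CPM (edgeR adjusted p = 0.00125 and 0.000568). CG5793 (FBgn0038858) and pps (FBgn0082831) were lower as well, at -1.18 ± 0.25 and -1.02 ± 0.29 (edgeR adjusted p = 0.00154 and 0.0125). Among higher genes, CG31875 (FBgn0051875) stood at 15.7 ± 1.17 CPM against 8.50 ± 1.54 in the inputs, a log2 fold of 1.03 ± 0.20 (edgeR adjusted p = 0.000885). Ts (FBgn0024920), thymidylate synthase, rose by 0.85 ± 0.26 to 261 ± 61.7 CPM, Asx (FBgn0261823), a Polycomb-group gene, by 1.02 ± 0.35 and CG4570 (FBgn0037844) by 0.77 ± 0.26 (edgeR adjusted p = 0.0183, 0.0334 and 0.0294).

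Across all genes, edgeR called 2968 for Rb5 against input, 1488 higher and 1480 lower, of which 840 rose and 694 fell at least 2-fold. Of the 80 tested genes with a symbol, 9 rose and 7 fell. Within the GA II class and within the class of replicate 3, folds correlated with the joint fit at r = 0.845 and 0.857 across genes, and 100% of called genes had the same direction. Leaving out Rb5 3 lowered the count to 1466, and with GA II libraries alone edgeR called 0 genes (1819 at an unadjusted p under 0.05), which ended every named call of this comparison. Over genes at 10 CPM or more in the inputs, 40.6% of calls were higher. The calls also ended for Ts and CG4570 without Kc input 2, Kc input 3, Rb5 1 or Rb5 3 (edgeR adjusted p from 0.0640 to 0.172). Those of pps ended without Kc input 2, Kc input 3 or Rb5 3 (edgeR adjusted p from 0.0606 to 0.102), and those of Asx without Kc input 1, Kc input 3 or any 1 Rb5 library (0.0558 to 0.103). Without the sequencing class the calls ended for Asx, pps and CG4570, and with only the compared groups for CG4570. Kc input 2 held 41.2 CPM of pps, and the other Kc inputs 10.8 to 20.2.

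Antiserum Rb6 gave Kc libraries with many of the same named genes at the ends of the range. Idgf3 stood at 34.1 ± 8.54 CPM (n = 2), a log2 fold of -2.29 ± 0.28 (edgeR adjusted p = 2.49e-05). Aldh (FBgn0012036), an aldehyde dehydrogenase, stood at 173 ± 5.65 CPM against 589 ± 177 in the inputs (n = 6), a log2 fold of -1.69 ± 0.29 (edgeR adjusted p = 0.000323). Mau2 fell by 1.46 ± 0.32, Prp31 by 1.36 ± 0.25, and Coa7 (FBgn0039965), a cytochrome c oxidase assembly factor, by 0.79 ± 0.23 (edgeR adjusted p = 0.00221, 0.000656 and 0.0134). CG31875 rose by 1.19 ± 0.22 to 21.5 ± 1.61 CPM, CG8516 (FBgn0037757) by 0.94 ± 0.23, CG12091 (FBgn0035228) by 0.89 ± 0.21 and CG4570 by 0.84 ± 0.29 (edgeR adjusted p = 0.000537, 0.00525, 0.00331 and 0.0360).

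In total edgeR called 2975 genes for Rb6, 1395 higher and 1580 lower, with 923 rises and 986 falls of at least 2-fold, and 6 rises and 10 falls among the genes with a symbol. Folds within each HiSeq class correlated with the joint fit at r = 0.819, with 99.7% to 100% of calls in the same direction. The count was 382 without Rb6 1, 1828 without Rb6 2 and 4587 with limma voom, an alternative added after seeing the data. Without Rb6 1 each named call ended except that of Idgf3 (edgeR adjusted p from 0.0581 to 0.336 for the others), and CG4570 was also lost without Kc inputs 4, 5 or 6 or Rb6 2 (0.0525 to 0.293 with Rb6 1). The replicate block ended the calls of CG8516, CG12091 and CG4570, and leaving out the class those of CG8516 and CG4570. In these settings the log2 folds were 0.22 and 0.60 for CG8516, 0.35 for CG12091, and 0.63 and 0.73 for CG4570.

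The third Shep antiserum, Gp01, had 8 named genes at its ends, of which CG12091 and Coa7 were also named with Rb6. AMPKalpha (FBgn0023169), the catalytic subunit of an energy-sensing kinase, stood at 55.4 ± 4.92 CPM (n = 2) against 22.3 ± 2.23 in the inputs (n = 6), a log2 fold of 1.26 ± 0.22 (edgeR adjusted p = 0.000727). CG9018 (FBgn0035318) stood at 93.0 ± 11.3 against 47.6 ± 9.56 CPM, a log2 fold of 1.21 ± 0.19 (edgeR adjusted p = 0.000350). MED1 (FBgn0037109), a Mediator subunit, rose by 1.04 ± 0.22 and Herc4 (FBgn0035207), a HECT ubiquitin ligase, by 0.81 ± 0.21 (edgeR adjusted p = 0.00319 and 0.0114). CG12091 rose by 0.77 ± 0.20 and Vps15 (FBgn0260935), a regulatory kinase of membrane traffic, by 0.76 ± 0.23 (edgeR adjusted p = 0.0133 and 0.0248). Pnn (FBgn0037737), the pinin homologue, fell by 1.18 ± 0.34 from 49.4 ± 8.49 to 20.8 ± 0.597 CPM and Coa7 by 0.66 ± 0.23 (edgeR adjusted p = 0.0186 and 0.0454).

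For Gp01 edgeR called 2009 genes, 988 higher and 1021 lower, with 578 rises and 681 falls of at least 2-fold, and 11 rises and 4 falls among the genes with a symbol. Folds within each HiSeq class correlated with the joint fit at r = 0.795 and 0.741, with 98.8% to 100% of calls in the same direction. The count was 1072 without Kc input 6, 235 without Gp01 1, 760 without Gp01 2 and 3654 with limma voom. MED1 was lost without Gp01 1 (edgeR adjusted p = 0.0882). Herc4, CG12091, Vps15 and Pnn were lost without any 1 of Kc input 6, Gp01 1 and Gp01 2 (edgeR adjusted p from 0.0559 to 0.311). Coa7 was lost without any 1 of Kc inputs 2, 4, 5 and 6, Gp01 1 and Gp01 2 (edgeR adjusted p from 0.0504 to 0.282). The replicate block or leaving out the class ended the calls of MED1, CG12091, Vps15 and Coa7. The HiSeq libraries alone ended those of Vps15, Pnn and Coa7, the compared groups alone those of Herc4, Vps15 and Coa7, and no filter those of CG12091, Vps15 and Coa7. Kc input 3 held 9.63 CPM of Vps15 and the other Kc inputs 5.26 to 6.10.

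The labels call the profiles of 2 Shep antibodies alike, and direct tests between the antisera were made after the data had been seen. Rb5 and Rb6 differed in 5 genes in edgeR (805 at an unadjusted p under 0.05), while 2159 genes differed between Rb5 and Gp01, 1109 of them higher with Rb5, and 2813 between Rb6 and Gp01, 1329 of them higher with Rb6. CG31875 was higher with Rb5 than with Gp01 by 2.30 ± 0.30 and with Rb6 than with Gp01 by 2.46 ± 0.26 on the log2 scale (edgeR adjusted p = 7.16e-05 and 6.03e-06). Gp01 itself was below input for this gene at -1.27 ± 0.24 (edgeR adjusted p = 0.00119). CG9018, Prp31 and Idgf3 went the other way, at -1.59 ± 0.25, -1.74 ± 0.30 and -1.42 ± 0.33 for Rb5 against Gp01 (edgeR adjusted p = 0.000293, 0.000662 and 0.00510). For Rb6 against Gp01 they stood at -1.93 ± 0.23, -1.94 ± 0.27 and -1.75 ± 0.30 (edgeR adjusted p = 1.12e-05, 4.92e-05 and 0.000258). AMPKalpha, MED1 and Mau2 were lower with Rb5 than with Gp01 as well, at -1.12 ± 0.29, -1.17 ± 0.29 and -1.43 ± 0.39 (edgeR adjusted p = 0.00931, 0.00732 and 0.0123). Rb5 shares no sequencing class with Rb6 or Gp01, so both comparisons with it rest on the inputs and Su(Hw) libraries that link the classes, while Rb6 and Gp01 share both of theirs. Against the Su(Hw) antiserum Gp60 in Kc cells, 820 genes differed for Gp01 and 1227 for Rb6.

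Across 9961 genes the folds of Rb5 and Rb6 against input correlated at r = 0.60 (Spearman's rho = 0.68), those of Rb5 and Gp01 at r = 0.23 (rho = 0.17) and those of Rb6 and Gp01 at r = 0.55 (rho = 0.39). Genes are not independent replicates, and shared inputs alone gave r = 0.10, 0.11 and 0.27 in simulations of unchanged groups. The covariances were 0.676, 0.272 and 0.745 beside simulated values of 0.0956, 0.109 and 0.340. With the inputs split between the comparisons, the median r was 0.43 (from -0.47 to 0.61 over the splits), 0.12 (-0.60 to 0.27) and 0.42 (0.28 to 0.47), so over all genes the sign of the correlations with Rb5 turned with the choice of inputs. Rb5 and Rb6 shared 885 rises and 1071 falls, beside 208 and 235 for independent lists, with 3 genes called in opposite directions. Rb5 and Gp01 shared 260 rises and 287 falls, beside 148 and 152, with 271 opposite, and Rb6 and Gp01 293 and 353, beside 138 and 162, with 190 opposite. Over the 5166 genes at 10 CPM or more in the inputs, a subset chosen after seeing the data, r was 0.83 for Rb5 and Rb6 (simulated 0.10), 0.14 for Rb5 and Gp01 (simulated 0.14) and 0.20 for Rb6 and Gp01 (simulated 0.24). With split inputs the medians over these genes were 0.79 (0.38 to 0.86), 0.08 (-0.15 to 0.18) and 0.15 (0.06 to 0.24). The covariances over these genes were 0.538, 0.0783 and 0.117 beside simulated values of 0.0741, 0.103 and 0.229. With Gp60 the correlations over these genes were r = 0.38 for Gp01 (simulated 0.27), 0.47 for Rb6 (simulated 0.14) and 0.34 for Rb5 (simulated 0.23).

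**Figure D2:**
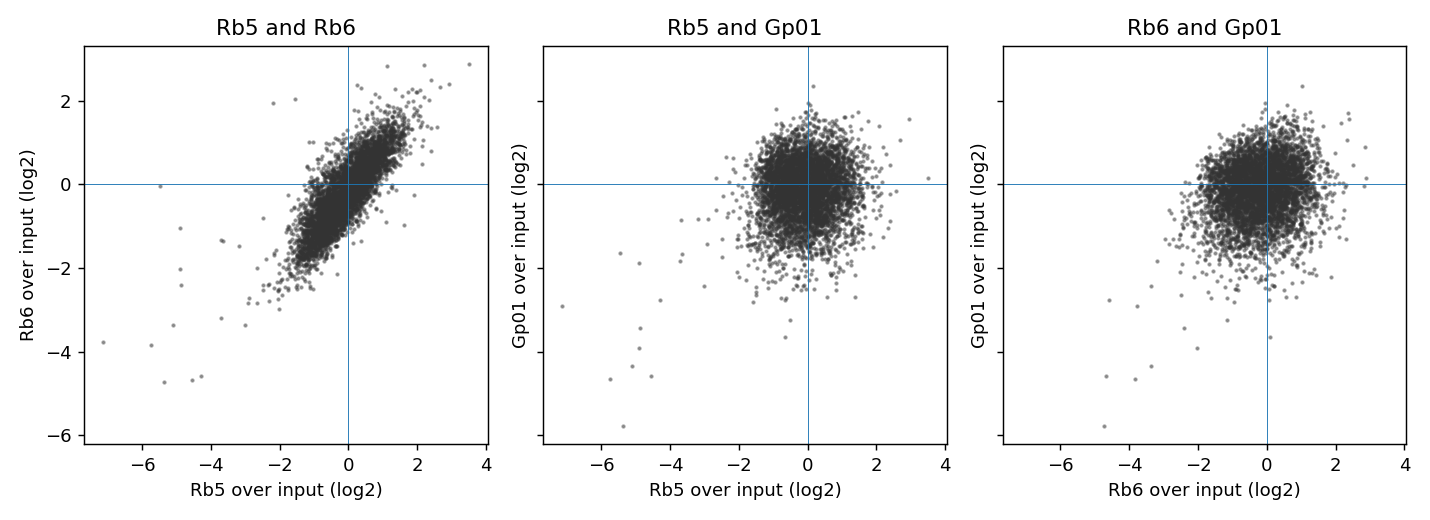
Log2 folds against Kc input for pairs of Shep antisera, with 1 point for each of 5166 genes at 10 CPM or more in the inputs and both axes in log2 units. Rb5 and Rb6 lie along the diagonal (r = 0.83), and Gp01 does not follow Rb5 (r = 0.14) or Rb6 (r = 0.20).

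The next comparison asks which RNAs were recovered with Su(Hw) in Kc nuclei. Idgf3 was lower at 71.6 ± 8.23 CPM (n = 3) against 162 ± 29.5 (n = 6), a log2 fold of -1.22 ± 0.22, and mfas (FBgn0260745), midline fasciclin, at -2.40 ± 0.69 (edgeR adjusted p = 0.00120 and 0.0244). Pnn fell by 1.19 ± 0.27, Mau2 by 1.13 ± 0.26 and CSN3 (FBgn0027055), a COP9 signalosome subunit, by 0.69 ± 0.16 (edgeR adjusted p = 0.00543, 0.00537 and 0.00643). The single named rise by the rule was lncRNA:CR43887 (FBgn0264479), at 11.1 ± 1.22 against 4.94 ± 1.17 CPM, a log2 fold of 1.22 ± 0.34 (edgeR adjusted p = 0.0149). Among genes with no symbol here, FBgn0003567 stood at 1777 ± 978 CPM against 18.5 ± 6.34, a log2 fold of 6.45 ± 0.42 (edgeR adjusted p = 2.95e-07). It was also higher with Su(Hw) in BG3 cells, at 5.55 ± 0.64, and was not called with Rb5 (0.31), Rb6 (-0.12) or Gp01 (-0.93) in Kc cells or Rb5 in BG3 cells (-0.38).

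With Kc Su(Hw), edgeR called 2412 genes, 1296 higher and 1116 lower, of which 855 rose and 361 fell at least 2-fold, and 12 rises and 8 falls were among the genes with a symbol. Over genes at 10 CPM or more in the inputs the balance turned, with 493 of 1591 calls higher, though this choice of genes can itself favour falls. Rises were also the smaller share under 6 other settings and without Kc input 1, Kc input 3 or Su(Hw) 2 (46.0%, 44.5% and 44.6%). Of the 4 sequencing classes, 3 hold 1 of these libraries each, and folds within those classes correlated with the joint fit at r = 0.591 (HiSeq with PHRED64, Su(Hw) 3), 0.748 (GA II, Su(Hw) 1) and 0.858 (mixed class, Su(Hw) 2). Of the called rises, 90.3%, 96.8% and 99.5% were higher there. The count was 1237 without Kc input 3, 1158 without Su(Hw) 1 and 1167 without Su(Hw) 2. It was 143 with HiSeq libraries alone, 1156 with the replicate block, 259 without Su(Hw) libraries Kc 1, Kc 2 and BG3 1, and 0 with GA II libraries alone (edgeR, 812 at an unadjusted p under 0.05). Each of the named calls with a symbol ended under those 2 platform subsets and without the 3 libraries. That of CSN3 also ended under the block and that of mfas with the compared groups alone, while the call of FBgn0003567 ended with GA II libraries alone. In addition, lncRNA:CR43887 was lost without Kc input 3, Su(Hw) 1 or Su(Hw) 2 (edgeR adjusted p = 0.0540 to 0.0758) and mfas without Kc input 1, Kc input 3, Su(Hw) 1 or Su(Hw) 3 (0.0512 to 0.129). Genes with under 0.05 CPM on average in the inputs summed to 685, 432 and 68.3 CPM of library totals in Kc Su(Hw) 1, 2 and 3, and to 284 and 143 in BG3 Su(Hw) 1 and 2.

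**Figure D3:**
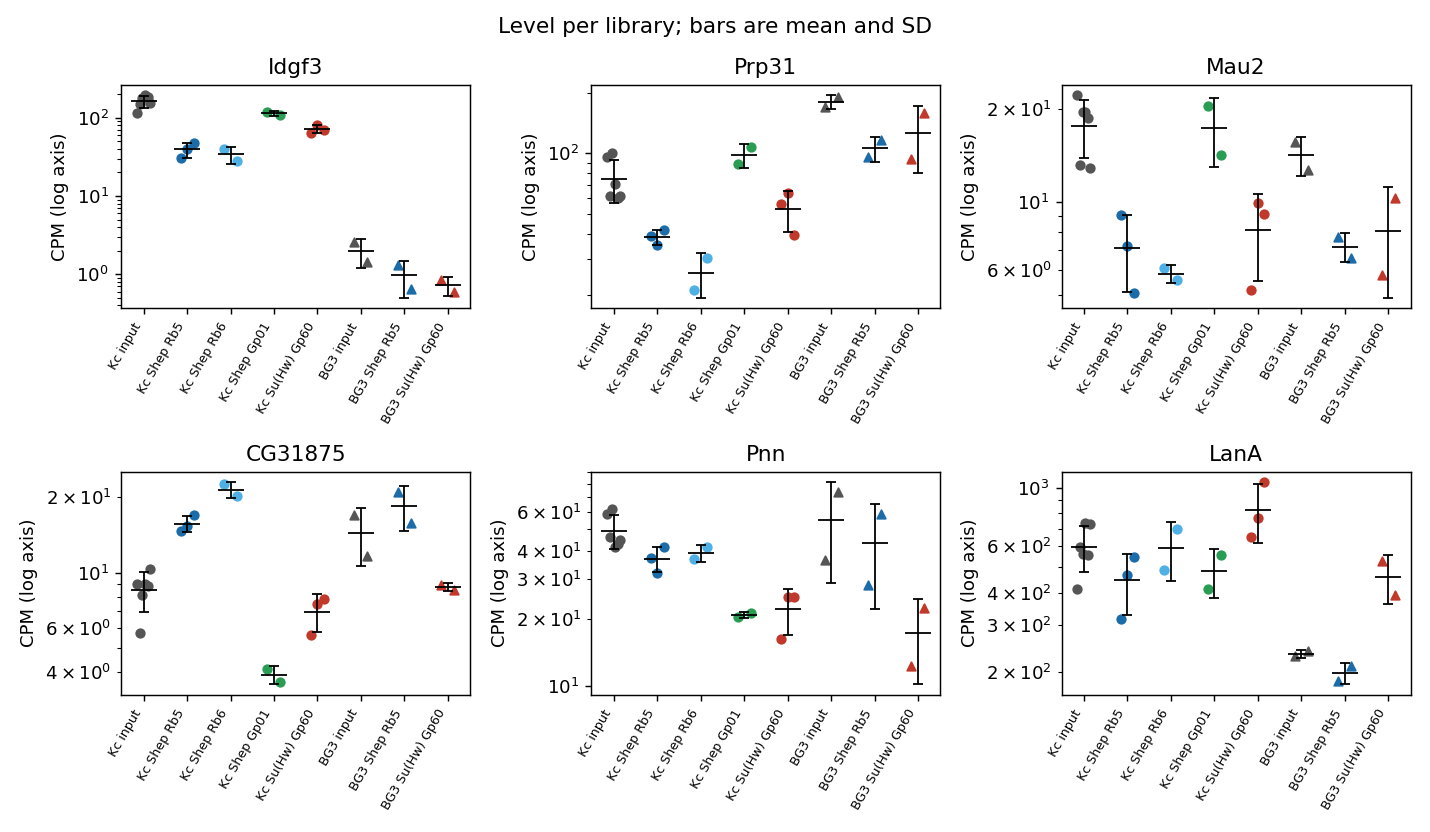
Level of Idgf3, Prp31, Mau2, CG31875, Pnn and LanA in each library by group, in TMM-scaled CPM on a log axis, with 1 point per library and bars for mean ± SD. Idgf3 stands at 162 ± 29.5 CPM in Kc inputs, 39.3 ± 8.33 with Rb5 and 1.99 ± 0.801 in BG3 inputs.

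In BG3 cells, few named genes passed the test with Shep antiserum Rb5. CG8516 stood at 16.2 ± 3.47 CPM (n = 2) against 7.18 ± 0.245 in the inputs (n = 2), a log2 fold of 1.17 ± 0.27 (edgeR adjusted p = 0.0116). CG42271 (FBgn0259166) and CG12091 rose by 0.80 ± 0.25 and 0.78 ± 0.23 (edgeR adjusted p = 0.0475 and 0.0381). Aldh was lower at 336 ± 57.8 against 646 ± 140 CPM, a log2 fold of -0.94 ± 0.30 (edgeR adjusted p = 0.0461). The count was 1094 genes, 620 higher and 474 lower, with 430 rises and 285 falls of at least 2-fold, and 4 rises and 1 fall among the genes with a symbol. All BG3 libraries are of 1 sequencing class, so no value within other classes can be given. This comparison depended on single libraries: 92 genes were called without BG3 input 1, 197 without Rb5 1 and 385 without Rb5 2. With only the compared groups edgeR called 0 genes (2095 at an unadjusted p under 0.05) while DESeq2 called 1775 over all libraries, and without the class the count was 304. CG8516 was lost without BG3 input 1 or Rb5 1 (edgeR adjusted p = 0.109 and 0.113), CG42271 and CG12091 without BG3 input 1, BG3 input 2 or Rb5 1 (0.105 to 0.468) and Aldh without BG3 input 1, Rb5 1 or Rb5 2 (0.114 to 0.340). All 4 named calls also ended without the class and with the compared groups alone, and all but that of CG8516 with the block, with limma voom or with no filter. Leaving out FBgn0085813 moved the share of higher genes among the calls from 56.7% to 46.4%, as genes at 10 CPM or more in the inputs did to 40.4%, and ended the calls of CG42271 and CG12091.

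Su(Hw) in BG3 cells recovered more of CG42271, at 26.8 ± 2.39 against 13.1 ± 1.78 CPM (n = 2 and 2), a log2 fold of 1.03 ± 0.25 (edgeR adjusted p = 0.00600). LanA (FBgn0002526), the laminin alpha chain, stood at 460 ± 96.8 against 234 ± 7.59 CPM, a log2 fold of 0.98 ± 0.28 (edgeR adjusted p = 0.0143). CG8516 rose by 0.83 ± 0.27 (edgeR adjusted p = 0.0297). Lower genes were Pnn at -1.65 ± 0.37, CSN3 at -1.12 ± 0.22, CG31875 at -0.72 ± 0.25 and Coa7 at -0.70 ± 0.25 (edgeR adjusted p = 0.00290, 0.00120, 0.0414 and 0.0441). There were 2740 calls, 1447 higher and 1293 lower, with 1212 rises and 830 falls of at least 2-fold, and 8 rises and 6 falls among the genes with a symbol. Over genes at 10 CPM or more in the inputs the balance turned, with 553 of 1843 calls higher, as it did with no filter and without FBgn0085813, BG3 input 1 or BG3 input 2. The count was 1506 without BG3 input 1 and 1369 without Su(Hw) 1, 838 with only the compared groups, 1783 without the class, 1385 with limma voom and 1302 without the 3 Su(Hw) libraries named above. Calls ended for Pnn without BG3 input 2 or Su(Hw) 1 (edgeR adjusted p = 0.0509 and 0.0589), and for CG42271 without BG3 input 2 (0.0619). They ended for LanA without BG3 input 1, BG3 input 2 or Su(Hw) 1 (edgeR adjusted p from 0.0621 to 0.136) and for CG8516 without any 1 of the 4 libraries (0.0534 to 0.152). They ended for CG31875 without BG3 input 1, Su(Hw) 1 or Su(Hw) 2 (edgeR adjusted p from 0.127 to 0.351) and for Coa7 without BG3 input 1, BG3 input 2 or Su(Hw) 1 (0.112 to 0.377). With only the compared groups all 7 calls ended, and without the 3 Su(Hw) libraries those of CG42271, LanA, CG8516, CG31875 and Coa7 did. The calls of CG8516, CG31875 and Coa7 also ended without the class and with limma voom, those of LanA, CG8516 and CG31875 with no filter, those of CG31875 and Coa7 with the block, and that of CG31875 with RLE.

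Rb5 and Su(Hw) precipitates were then set against each other. Protein and antiserum change together here, so a difference between proteins cannot be told from one between antisera. Antisera Rb6 and Gp01, both against Shep, differed in 2813 genes. In Kc cells Ts stood at 261 ± 61.7 CPM with Rb5 (n = 3) and 99.2 ± 1.40 with Su(Hw) (n = 3), a log2 difference of 1.48 ± 0.28 (edgeR adjusted p = 0.000999). CG31875 and CG4570 were higher with Rb5 by 1.28 ± 0.23 and 1.02 ± 0.29 (edgeR adjusted p = 0.000531 and 0.0140). CG8516 and CSN3 differed by 0.65 ± 0.23 and 0.51 ± 0.19 (edgeR adjusted p = 0.0472 and 0.0489). CG5793 was lower with Rb5 at 19.9 ± 2.85 against 53.1 ± 16.7 CPM, a log2 difference of -1.66 ± 0.26 (edgeR adjusted p = 0.000214). So were CG42271 at -0.93 ± 0.22, Idgf3 at -0.74 ± 0.25 and LanA at -0.73 ± 0.24 (edgeR adjusted p = 0.00479, 0.0332 and 0.0287). Of 2645 genes called, 1263 were higher with Rb5 and 1382 with Su(Hw), 739 and 935 of them at least 2-fold, and 5 and 11 among the genes with a symbol. Within the GA II and the mixed class, differences correlated with the joint fit at r = 0.778 and 0.881. The count was 1193 without Rb5 3, 1480 without Su(Hw) 1, 1365 without Su(Hw) 2, 1665 without the class and 1557 with the compared groups alone. It was 2 with GA II libraries alone and 355 without the 3 Su(Hw) libraries, and these last 2 settings ended all 9 named calls. The call of CSN3 also ended under 5 other settings, among them RLE and the block, that of CG8516 with RLE, that of CG4570 without the class, those of Idgf3 and LanA with no filter or without FBgn0085813, and that of LanA with the compared groups alone. Single libraries ended the call of CG42271 (Rb5 3, edgeR adjusted p = 0.0724) and those of CG4570 and Idgf3 (Rb5 1, Rb5 3, Su(Hw) 1 and Su(Hw) 2, 0.0624 to 0.170). They also ended that of CG8516 (Rb5 2, Rb5 3, Su(Hw) 1 and Su(Hw) 2, edgeR adjusted p from 0.0970 to 0.275) and those of CSN3 and LanA (Rb5 1, Rb5 3 and each Su(Hw) library, 0.0617 to 0.207).

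In BG3 cells Pnn was higher with Rb5 than with Su(Hw) by 1.31 ± 0.36, CG31875 by 1.08 ± 0.25 and snama (FBgn0086129) by 0.98 ± 0.30 (edgeR adjusted p = 0.0200, 0.00791 and 0.0340). LanA was lower at 197 ± 18.7 against 460 ± 96.8 CPM (n = 2 and 2), a log2 difference of -1.22 ± 0.28 (edgeR adjusted p = 0.00649). Of 1427 genes called, 770 were higher with Rb5 and 657 with Su(Hw), 530 and 554 of them at least 2-fold, and 4 and 4 among the genes with a symbol. The count was 470 without Rb5 2, 430 without Su(Hw) 1, 237 with the compared groups alone, 903 without the class, 655 with limma voom and 411 without the 3 Su(Hw) libraries. Calls of Pnn and snama ended without Rb5 2 or Su(Hw) 1 (edgeR adjusted p = 0.248 to 0.351), those of CG31875 and LanA without Rb5 1 or Su(Hw) 1 (0.0594 to 0.0895), and all 4 with the compared groups alone or without the 3 Su(Hw) libraries. Pnn and snama were not called with limma voom, nor snama without the class.

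**Figure D4:**
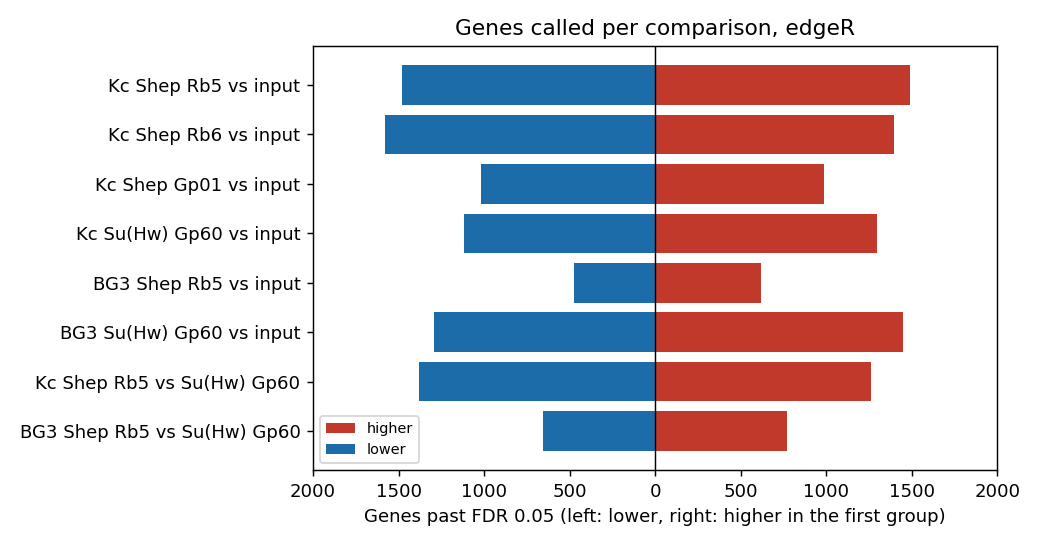
Number of genes called higher and lower by edgeR in each comparison of a precipitate with input or of Rb5 with Su(Hw), as bars that start at 0. The comparison of inputs and the interactions are not drawn. The totals of higher and lower genes run from 1094 for BG3 Rb5 against input to 2975 for Kc Rb6 against input.

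The inputs themselves show which nuclear RNAs differ between the lines. Idgf3 stood at 1.99 ± 0.801 CPM in BG3 inputs (n = 2) and 162 ± 29.5 in Kc inputs (n = 6), a log2 difference of -6.51 ± 0.37 (edgeR adjusted p = 4.26e-11). CG4570 was lower in BG3 at -3.58 ± 0.36, Ant2 (FBgn0025111), an ADP/ATP translocase, at -3.24 ± 0.42, Boot (FBgn0033374) at -2.26 ± 0.43 and pps at -2.01 ± 0.37 (edgeR adjusted p = 1.37e-07, 4.51e-06, 0.000321 and 0.000232). Prp31 was higher in BG3 at 179.8 ± 14.5 against 74.9 ± 18.2 CPM, a log2 difference of 1.57 ± 0.23 (edgeR adjusted p = 1.77e-05). Next came CG12091 at 1.16 ± 0.21, CG2200 (FBgn0030447) at 1.101 ± 0.32, Herc4 at 0.91 ± 0.21 and CG9018 at 0.89 ± 0.20 (edgeR adjusted p = 0.000162, 0.00900, 0.00163 and 0.00110). EdgeR called 4242 genes, 2379 higher in BG3 and 1863 higher in Kc, 1845 and 1394 of them at least 2-fold, and 18 and 24 among the genes with a symbol. The lines share 1 sequencing class, HiSeq with PHRED64, and HiSeq libraries alone gave 3958 calls. The count was 2766 with the inputs fitted alone and 1582 over genes at 10 CPM or more. The call of CG2200 ended without BG3 input 1 (edgeR adjusted p = 0.521), without the class and with the block, that of Herc4 with the inputs alone and that of CG9018 with the block.

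Whether enrichment over input differed between the lines was tested as an interaction. Rb5 libraries of the lines share no sequencing class, so class and line are kept apart only by the Kc inputs and Kc Su(Hw) libraries that link the classes. For Rb5, edgeR called 9 genes, 3 with a higher fold in BG3 and 6 with a lower one (1026 at an unadjusted p under 0.05), and 0 of the genes with a symbol were called (DESeq2 called 125 genes in all, 74 of them with a higher fold in BG3). For Su(Hw) it called 258, 201 with a higher fold in BG3 and 57 with a lower one, and 1 of the genes with a symbol, Mlp60A (FBgn0259209), a muscle LIM protein, at 5.70 ± 1.201 (edgeR adjusted p = 0.0142). The Rb5 count was 1 without BG3 input 1, 3 without BG3 input 2, 0 without BG3 Rb5 1 and 3 without Kc input 1. It was 1 without Kc input 3, 5 without Kc input 6, 4 without Kc Rb5 2 and 0 without Kc Rb5 3 (edgeR, 555 and 662 genes at an unadjusted p under 0.05 for these counts of 0). It was also 0 without the class (577 at an unadjusted p under 0.05), 109 with no filter, 83 of them with a higher fold in BG3, and 2 with limma voom. It was 3 with the block and 4 with the compared groups alone or over genes at 10 CPM or more. The Su(Hw) count was 44 without BG3 input 1, 166 without BG3 input 2, 89 without BG3 Su(Hw) 1, 430 without BG3 Su(Hw) 2, 124 without Kc input 3, 152 without Kc Su(Hw) 1 and 127 without Kc Su(Hw) 2. It was 588 with DESeq2, 462 with no filter, 155 without the class, 104 with limma voom, 78 with the compared groups alone, 44 over genes at 10 CPM or more, 31 without the 3 Su(Hw) libraries and 25 with HiSeq libraries alone. The call of Mlp60A ended without BG3 input 1, BG3 input 2 or BG3 Su(Hw) 1 (edgeR adjusted p = 0.0582 to 0.0983, log2 differences from 3.68 to 8.98), and with the compared groups alone, HiSeq libraries alone, limma voom or without the 3 Su(Hw) libraries.

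Of the 17 gene lists, 4 held a gene with a symbol, and the other 13 held none and have no result here. The haemocyte list held LanA and gcm2 (FBgn0019809). LanA was called in 4 of the comparisons, higher with Su(Hw) in BG3 cells, lower with Rb5 than with Su(Hw) in both lines, and lower in BG3 than in Kc inputs at -1.48 ± 0.26 (edgeR adjusted p = 0.000162). With Su(Hw) in Kc cells it stood at 0.54 ± 0.20 (edgeR adjusted p = 0.0520). Gcm2 averaged 0.338 CPM or less in each group. It was called lower with Rb5 (0 counts in 3 libraries) than with Su(Hw) in Kc cells (0.194 ± 0.231 CPM), and higher in BG3 inputs (0.191 ± 0.0790 CPM) than in Kc inputs, where 1 of 6 libraries held 1 count (edgeR adjusted p = 0.0191 and 0.00397). No fold is given against these counts. The former call ended without Rb5 3, Su(Hw) 1 or Su(Hw) 2 (edgeR adjusted p from 0.128 to 0.158), without the class, with the block and without the 3 Su(Hw) libraries (0.0502 to 1), and the latter with the block (0.103).

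Of the Polycomb and trithorax list, Asx was called with Rb5 in Kc cells and with Su(Hw) in BG3 cells, at 1.39 ± 0.46 from 3.02 ± 1.86 to 7.77 ± 2.50 CPM (edgeR adjusted p = 0.0331). It was lower in BG3 than in Kc inputs at -1.48 ± 0.44 (edgeR adjusted p = 0.0105). Those calls of Asx ended without BG3 input 1 or Su(Hw) 2 (edgeR adjusted p = 0.206 and 0.280) and without BG3 input 1 (0.155), and the Su(Hw) call also with the compared groups alone (edgeR 0.105) and with limma voom (0.0824). Of the nuclear noncoding RNAs, lncRNA:roX1 (FBgn0019661), a dosage compensation RNA, was at 0.0407 ± 0.0462 CPM in Kc inputs, 0.253 ± 0.0910 with Gp01 and 0.655 ± 0.514 with Kc Su(Hw). These are log2 folds of 3.62 ± 0.93 and 3.41 ± 0.84 at these low counts (edgeR adjusted p = 0.0106 and 0.00821), and the calls ended without Gp01 1 (edgeR adjusted p = 0.285) and without Kc input 3 or Su(Hw) 2 (0.0821 to 0.123). The Gp01 call of lncRNA:roX1 also ended with the block and with the compared groups alone (edgeR adjusted p from 0.0566 to 0.354, log2 folds from 1.67 to 2.80). The Su(Hw) call also ended with HiSeq libraries alone and without the 3 Su(Hw) libraries (log2 folds of 1.63 and 1.64). It was also lower with Rb5 than with Su(Hw) in Kc cells at -4.01 ± 0.99, and higher in BG3 than in Kc inputs at 3.33 ± 1.00 (edgeR adjusted p = 0.00617 and 0.0114). The former call ended without Rb5 3, Su(Hw) 2 (edgeR adjusted p from 0.200 to 0.211) or the 3 Su(Hw) libraries (0.757), and the latter without BG3 input 2 (0.221), with the block and with HiSeq libraries alone (0.0728 to 0.307).

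Of the muscle list, Mlp60A was at 2.69 ± 2.93 CPM with BG3 Su(Hw) against 0.0275 ± 0.0389 in the inputs, a log2 fold of 6.25 ± 1.01 (edgeR adjusted p = 0.000287). The alternatives moved this fold from 4.14 to 9.52 and left it called, so its size is uncertain at these low counts. It was at -5.40 ± 0.88 for BG3 Rb5 against Su(Hw) (edgeR adjusted p = 0.000516), a call that ended with the compared groups alone (0.0587). The call of Mlp60A in BG3 against Kc inputs, at -3.86 ± 1.01 (edgeR adjusted p = 0.00454), ended without BG3 input 2 (0.0542). Kc input 1 held 0.189 CPM of Mlp60A and the other Kc inputs 0.467 to 0.615.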

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

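The tests of sequencing class and of FBgn0085813 and the use of genes that are nearly absent from the inputs were chosen after the result was seen. So were the alternatives limma voom, leaving out FBgn0085813 and leaving out 3 Su(Hw) libraries.

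Some Su(Hw) libraries held many counts in genes that the inputs nearly lack. Over 6518 genes averaging under 0.05 CPM in the inputs, the sums were 685 CPM in Kc Su(Hw) 1, 432 in Kc Su(Hw) 2 and 284 in BG3 Su(Hw) 1, with 68.3 and 143 CPM in Kc Su(Hw) 3 and BG3 Su(Hw) 2, 34.1 to 95.9 in inputs left out of the choice of genes and 109 to 212 in Shep libraries. The choice of genes by low input counts is argued against as the cause, since the highest input left out of it reached 95.9 CPM beside 293 in the lowest of the 3 libraries, and sequencing class is argued against for Kc 1 and Kc 2, since other Kc libraries of their classes reached at most 166.5 CPM. An even background over all genes stays open, because the 10 leading genes held 2.66% and 2.05% of the sum in Kc 1 and Kc 2 but 16.3% in BG3 1. No biological explanation was tested.

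Reads that fell in more than 1 gene made up 2.79% of the gene and ambiguous counts in the Kc Rb5 libraries on average, above the 1.76% to 2.13% of the 6 Kc inputs, in data that no comparison uses. The means were 3.035% with Rb6, 2.93% with Gp01 and 2.07% with Kc Su(Hw). In BG3 cells they were 2.67% with Rb5, 2.09% with Su(Hw) and 1.77% in the inputs. Leaving out FBgn0085813 lowered the ratio of Rb5 to input from 1.45 to 1.18, which argues against this identifier as the whole cause. Within sequencing classes the ratios were 1.42 and 1.57, which argues against the class. What accounts for the remaining ratio of 1.18 was not tested, and neither was a biological explanation.

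Reads placed at more than 1 position made up 64.1% of all counts in Kc input 6, far above the 35.1% to 42.5% of the other Kc inputs. It is the only input sequenced on HiSeq with PHRED33 qualities, and the other libraries of that class held 63.8% (Rb6 2) and 79.6% (Gp01 2). The level of pps in Kc input 2 was 41.2 CPM, against 10.8 to 20.2 in the others. Vps15 stood at 9.63 CPM in Kc input 3, against 5.26 to 6.10. The level of gcm2 was 0.0238 CPM in Kc input 5 and 0 in the others. Mlp60A stood at 0.189 CPM in Kc input 1, against 0.467 to 0.615. These are 5 of 36 quantities checked in the 6 Kc inputs for a single library far from the rest, where chance gives about 5% per check.

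The enrichment over input differed between cell lines for 5 of the genes described, each by an interaction test. For Rb5, FBgn0052423, which has no symbol here, had a difference of 3.72 ± 0.66 (edgeR adjusted p = 0.0361). It was lost without any 1 of 10 libraries, with differences from 3.30 to 4.28. These were BG3 inputs 1 and 2, BG3 Rb5 1 and 2, Kc inputs 1, 3 and 6, and Kc Rb5 1, 2 and 3. It was also lost without the class, with limma voom and without FBgn0085813 (adjusted p from edgeR or limma of 0.0513 to 0.184). FBgn0036891 had -2.99 ± 0.40 (edgeR adjusted p = 0.00378), with 58.8 ± 0.291 CPM with BG3 Rb5, 61.7 ± 1.92 in BG3 inputs, 6.12 ± 1.51 with Kc Rb5 and 1.70 ± 1.02 in Kc inputs, lost without BG3 Rb5 1 or Kc Rb5 3 (0.0603 and 0.0616). Without the class it stood at -1.84 (edgeR adjusted p = 0.685). For Su(Hw), FBgn0082957 had 9.43 ± 1.35 (edgeR adjusted p = 0.00360), with 793 ± 922 CPM over the 2 BG3 Su(Hw) libraries against 8.11 ± 1.16 in BG3 inputs, and it was lost without BG3 input 1 (0.0513) and with HiSeq libraries alone (0.162). FBgn0036587 had -6.45 ± 1.105 (edgeR adjusted p = 0.00938), a value that depends on the prior count because the Kc inputs held 0 counts of it, with 8.89 ± 2.11 CPM with BG3 Su(Hw) and 36.1 ± 3.76 in BG3 inputs, and it was lost without Kc input 3 or Kc Su(Hw) 2 (0.0810 and 0.391). FBgn0036587 was also lost with the replicate block, with HiSeq libraries alone and without the 3 Su(Hw) libraries (edgeR adjusted p from 0.0835 to 1, with values from -6.93 to -1.74). Mlp60A had 5.70 ± 1.201, with limits given in the results.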

How the results depend on the processing

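The alternatives limma voom, leaving out FBgn0085813, genes at 10 CPM or more in the inputs, and leaving out Su(Hw) libraries Kc 1, Kc 2 and BG3 1 were tests chosen after the results were seen; the others were planned. Over 101 gene results, 1381 of 1724 alternative values stayed in direction and past the threshold, 342 lost significance and 1 reversed. By setting, calls kept and ended were 98 and 3 with RLE, 101 and 0 with DESeq2, 89 and 12 with no filter, 78 and 23 without the class, 78 and 23 with the replicate block, 65 and 31 with the compared groups alone, 90 and 11 with limma voom, 96 and 5 without FBgn0085813, 66 and 0 over genes at 10 CPM or more, 35 and 16 with HiSeq libraries, 1 and 29 with GA II libraries, and 12 and 30 without the 3 Su(Hw) libraries. Leaving out 1 library kept 572 of 731 and ended 159. The gene that reversed was gcm2 in Kc Rb5 against Su(Hw), at 2.40 without the 3 Su(Hw) libraries, with no counts in the Rb5 libraries. Among list members that had not passed, 66 of 655 alternative values over 38 pairs of gene and comparison had the other sign and 18 were called, so their values are not read as rises or falls, a choice made after seeing the alternatives. The direct tests between antisera were not recomputed under the alternatives. The 5 GA II libraries hold from 6190633 to 12498109 gene counts, the lowest depths here.

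Counts of genes called that moved by over 1.5 times follow, and the cause was not tested except where fewer libraries or genes entered by construction. GA II libraries alone gave 0 for Rb5 and 0 for Su(Hw) in Kc (edgeR, 1819 and 812 at an unadjusted p under 0.05, with no other tool run) and 2 between them, against 2968, 2412 and 2645. HiSeq libraries alone gave 143 for Kc Su(Hw) and 25 for its interaction. The replicate block gave 1156 for Kc Su(Hw) and 3 for the Rb5 interaction, moved no other count by over 1.5 times (Kc Rb5 2505) and ended 0 of the named Kc Rb5 calls. Su(Hw) and input numbers did not deviate together. The block crosses cell lines and sequencing classes, so these values do not test pairing. The compared groups alone gave 1539 for Kc Su(Hw), 0 for BG3 Rb5 (edgeR, 2095 at an unadjusted p under 0.05, and 1775 by DESeq2 over all libraries), 838 for BG3 Su(Hw), 1557 and 237 for Rb5 against Su(Hw) in Kc and BG3, 2766 for inputs, and 4 and 78 for the Rb5 and Su(Hw) interactions. Without the class there were 304 for BG3 Rb5, 1783 for BG3 Su(Hw), 1665 and 903 for Rb5 against Su(Hw), and 0 (edgeR, 577 at an unadjusted p under 0.05, DESeq2 125 with the class) and 155 for the interactions. DESeq2 gave 1775 for BG3 Rb5 and 125 (74 higher in BG3) and 588 for the interactions, and no filter 109 (83 higher in BG3) and 462. Limma voom gave 4587 for Rb6, 3654 for Gp01, 1385 for BG3 Su(Hw), 655 for BG3 Rb5 against Su(Hw), and 2 and 104 for the interactions. Genes at 10 CPM or more gave 1591 for Kc Su(Hw), 1582 for inputs, and 4 and 44 for the interactions. Without the 3 Su(Hw) libraries there were 259 for Kc Su(Hw), 1302 for BG3 Su(Hw), 355 and 411 for Rb5 against Su(Hw), and 31 for the Su(Hw) interaction.

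Leaving out 1 library gave counts from 1466 to 2889 for Kc Rb5, 382 to 3068 for Rb6, 235 to 2028 for Gp01, 1158 to 2532 for Kc Su(Hw), 92 to 891 for BG3 Rb5, 1369 to 2873 for BG3 Su(Hw), 1193 to 2504 and 430 to 1894 for Rb5 against Su(Hw) in Kc and BG3, 3334 to 4286 for inputs, and 0 to 8 and 44 to 430 for the interactions. Correlations of antisera moved to 0.337 for Rb5 and Rb6 with no filter, 0.433 with split inputs and 0.825 at 10 CPM or more. For Rb5 and Gp01 they were 0.132, 0.118 and 0.139, and 0.387 without the class, and for Rb6 and Gp01 0.407 without the class, 0.4155 with split inputs and 0.196 at 10 CPM or more. Without FBgn0085813 the share of higher genes went from 56.7% to 46.4% for BG3 Rb5 and from 33.3% to 10% for the Rb5 interaction, where the median of all genes moved by -0.126. At 10 CPM or more the share of higher genes was 31.8% for Rb6, 38.3% for Gp01, 31.0% for Kc Su(Hw), 40.4% for BG3 Rb5, 30.01% for BG3 Su(Hw) and 67.8% for BG3 Rb5 against Su(Hw). RLE moved no share by over 10 points. Whether rises or falls were more numerous turned under at least 1 alternative in each comparison except that of the inputs and the Su(Hw) interaction.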

Other observations

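The comparisons across cell lines, the tests of sequencing class and of Gp60, and the tests of library composition in this part were chosen after the result was seen. The test for a mislabelled library and the other splits were written down before.

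Several named genes were called in the same direction in both cell lines. With Su(Hw), Pnn, CSN3 and Idgf3 were lower in Kc (-1.19 ± 0.27, -0.69 ± 0.16 and -1.22 ± 0.22) and in BG3 (-1.65 ± 0.37, -1.12 ± 0.22 and -1.56 ± 0.39, edgeR adjusted p = 0.00611 for Idgf3). Nasp (FBgn0037624), a histone chaperone, was lower as well, at -1.52 ± 0.50 and -2.27 ± 0.63 (edgeR adjusted p = 0.0331 and 0.0129). It stood at 3.60 ± 1.44 CPM in Kc inputs (n = 6) and 7.45 ± 3.93 in BG3 inputs (n = 2). With Rb5, Aldh was lower in Kc at -0.83 (edgeR adjusted p = 0.0113) and in BG3 at -0.94 ± 0.30, while Idgf3 stood at -1.96 ± 0.24 in Kc and -1.03 in BG3 (edgeR adjusted p = 0.0505). Nasp was also lower with Rb6 at -2.26 ± 0.60 (edgeR adjusted p = 0.00802) and was not called with Rb5 in either line or with Gp01. Nasp, and Idgf3 and Aldh where the results do not give them, were chosen after their values were seen and were not recomputed under the alternatives.

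Across 9961 genes, folds against input in Kc and BG3 correlated at r = 0.43 for Rb5 and 0.47 for Su(Hw), where simulated unchanged groups gave 0.02 and 0.04, with covariances of 0.410 and 0.795 beside simulated values of 0.0203 and 0.0463. Genes are not independent replicates. Between proteins, Kc Su(Hw) and BG3 Rb5 correlated at r = 0.42 (simulated -0.02), close to the values for the same antiserum. Kc Rb5 and BG3 Su(Hw) correlated at r = 0.04 (simulated -0.05). Rb5 shared 406 rises and 388 falls between lines, beside 92.6 and 70.4 for independent lists, with 7 opposite, and Su(Hw) shared 513 and 710, beside 188 and 145, with 27 opposite. Over the 5166 genes at 10 CPM or more in the Kc inputs, whatever their level in BG3, r was 0.70 for Rb5 (simulated 0.04) and 0.65 for Su(Hw) (simulated 0.06). Within BG3, Rb5 and Su(Hw) correlated at r = 0.56 where the shared inputs alone gave 0.52, with covariances of 0.798 and 0.760, and 2 inputs are too few to split.

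Reads in no annotated gene made up 25.4% of uniquely placed reads with Rb5 and 22.9% with Su(Hw) in Kc, against 45.1% in the inputs, and FBgn0085813 held 4.17% and 7.47% of gene counts against 22.05% (n = 3, 3 and 6). Each of these 4 differences had an exact two-sided permutation p of 0.0238, the smallest that 3 against 6 can give, and an adjusted p of 0.0397 in a family of 10 tests. For Rb5 these p-values ignore a possible pairing with the inputs, and 3 pairs alone could not reach 0.05. FBgn0085813 was the most abundant identifier in 20 of the 22 libraries, with 3.09% to 30.1% of their gene counts.

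Antiserum Gp01 stood apart from Rb5 and Rb6 in the direct tests and over genes at 10 CPM or more. Over all 9961 genes the contrast was weaker. There Rb6 and Gp01 correlated at r = 0.55 (simulated 0.27), Rb5 and Gp01 at 0.23 (simulated 0.11) and Rb5 and Rb6 at 0.60 (simulated 0.10). A sequencing class is argued against as the cause, because 2813 genes differed between Rb6 and Gp01, which share their classes, and 5 between Rb5 and Rb6. A mislabelled Gp01 library is argued against too, because the highest correlation of a Gp01 library with an Rb5 or Rb6 library was 0.371 and the 2 Gp01 libraries correlated at 0.704. A background shared with the Su(Hw) antiserum Gp60 stays open: over genes at 10 CPM or more the covariance of Gp01 with Gp60, less its simulated value, was -0.0437, below the 0.135 of Rb6 with Gp60, but over all genes the matching values were 0.682 and 0.659, and Gp01 differed from Gp60 in 820 genes, fewer than Rb6 from Gp60 (1227). No biological explanation was tested.

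Other splits of the same libraries bear on the Kc counts. Of 84 splits of the 9 Rb5 and input libraries, 1, the real one, gave as many as 2968 genes, and the highest of the others gave 1473. That split set Kc inputs 1 to 3 against the rest and parts the libraries of the classes that hold both groups as the real one does, and the next gave 93. The 84 splits take no account of the sequencing classes, and those that keep the classes of the real split are too few for a share under 0.05. So are the 8 splits that part as many pairs of like replicate number, among them the real one and the highest other. Chance is therefore not excluded for Rb5. Of 84 splits of the 9 Su(Hw) and input libraries, 1, the real one, gave as many as 2412, and the highest other, again inputs 1 to 3, gave 1109. Splits that keep the classes of the real one are again too few for a share under 0.05, so chance is not excluded for Su(Hw) either. For Rb5 against Su(Hw), 10 splits are too few for a share under 0.05, and the real split gave 2645 genes and the highest other 1.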
